A study of Mus musculus with 17 samples.

How the data were processed

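RNA was measured in 17 bone marrow libraries from mice with leukemia. Per the labels, lineage-depleted mouse marrow was transduced with retroviral constructs and transplanted 48 h later into lethally irradiated syngeneic recipients, and marrow was taken when the recipients were moribund. The groups are the transduced drivers: CIC-NUTM2A (n = 5), AML1-ETO9a (n = 3), CBFA2T3-GLIS2 together with an activating JAK2 (n = 3, written CBFA2T3-GLIS2/Jak2, which the titles spell CBAF2T3-GLIS2/Jak2), NUP98-KDM5A (n = 3) and MLL-AF6 (n = 3). Each library was placed in its group by its title. No library of normal marrow or of an empty vector was analysed here, so every difference is between drivers. The labels number the libraries within a driver without saying that each came from a separate mouse, and p-values therefore measure the spread between these libraries.

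RNA was extracted with Trizol and sequenced with an Illumina stranded total RNA kit, per the labels' protocols. The submitters' processing notes name BWA and HTSeq, without versions. The genome build and the annotation are not given in the sources used here, so no coordinates are reported, and genes are named by the symbols of the deposited table. The authors deposited a signal per gene, the reads of the gene divided by a total of the library, for 34590 genes, with 1 column per library and no pooled column. Per the file headers these values are FPKM, but 1 read has the same value in every gene of a library, so they carry no scaling by gene length. They are written RPM here, reads per 1e6 of the total by which the library was scaled, and levels of different genes reflect gene length too. Of these genes, 4884 were at 0 in every library.

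Depth was recovered from the values themselves. Every value is a whole multiple of the smallest value above 0 of its library, which is that of 1 read, and 100.0% of the 372728 values above 0 came out whole within 0.001 reads. The recovery was tested on simulated data, where it returned 10000 of 10000 genes. Recovered reads per library ran from 23.9 M (CBFA2T3-GLIS2/Jak2 replicate 1) to 74.8 M (CIC-NUTM2A replicate 3), and 1 read was worth 0.0154 to 0.0538 RPM. All recovered reads were 1.12 to 1.46 times the total by which their library had been scaled, and those of 19251 protein-coding symbols (GENCODE M21) were 0.916 to 0.935 times it. Strand handling during counting is not stated, and genes with near-identical copies, such as Hspa1a with Hspa1b and Hba-a1 with Hba-a2, are uncertain because reads could be split between the copies.

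Values were transformed to log2(RPM + 1), which understates the fold difference of genes with low values. The transform and the test had been chosen for FPKM values before the data were examined and were kept for the scaled reads. Genes at 1 RPM or more in at least 3 libraries were tested, 16804 in all. One linear model with a mean per group was fitted to the 17 libraries with limma (version 3.58.1, R 4.3.3, empirical Bayes with trend and robust settings), so that groups of 3 shared an estimate of the spread. Tables and figures were made with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. A gene was called when its Benjamini-Hochberg adjusted p was under 0.05 and its log2 difference was at least 1 in size. The comparisons were CIC-NUTM2A against the mean of the 4 other drivers, CIC-NUTM2A against each of them, and each other driver against the mean of the 4 remaining groups. The pairwise comparisons share the CIC-NUTM2A libraries, so the overlap of their calls was set against 20 simulations of unchanged groups, against independent lists, and against splits of the CIC-NUTM2A libraries. On simulated data with 100 changed genes per fold size, 92.3 of 100 genes with a 4-fold change were called for CIC-NUTM2A against the mean of the others and 93.3 of 100 against AML1-ETO9a, with 0 false calls in each. For 2-fold changes 30.3 and 30.7 of 100 were called, since a change of that size lies at the minimum difference. These simulations drew all groups around 1 mean per gene, apart from the changed genes, with a dispersion of 0.05 for every gene. Genes such as Chi3l3 and Mrc1 spread more between the real libraries, so these rates need not hold for the data.

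Before the data were examined, 27 gene lists with 399 symbols were fixed. They cover genes of the constructs, known CIC targets and feedback genes of ERK signalling, the HOXA and HOXB clusters, stem and progenitor genes, markers of blood and stromal cell types, and programmes such as proliferation, interferon response and immediate early genes. Among the deposited symbols, 397 were found, 14 of them by an older symbol. Lists with at least 3 tested members were tested with limma's camera at an inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated from the data. No list call in any comparison held with the estimated correlation, and the adjusted p found with it is given beside each call. Ranges of adjusted p over alternatives leave out the estimated correlation, under which every call ended, and limma's fry, which asks a different question. The ranges therefore do not show how far a list call depends on the assumed correlation. Library similarity was tested with 100000 permutations, and the mouse genes named in the constructs with exact permutation tests.

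The genes named in the text follow a rule fixed before the data were examined. It takes all construct genes; the 10 called genes with the largest positive and the 10 with the largest negative log2 difference for CIC-NUTM2A against the mean of the others, where every CIC-NUTM2A library lay beyond every other library; the 4 largest and 4 lowest against each driver and the 5 largest and 5 lowest for each other driver, also without overlap; and up to 6 members of each list with the largest moderated t, with the CIC target, HOXA and promyelocyte lists open in full. Predicted genes, pseudogene-like names, receptor segments, small RNAs and sex-linked genes were left out of the ranked parts. Some genes that the rule takes are not named in the text, and Malat1, Neat1 and the genes added for single tests were named outside it.

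Alternatives fixed before the data were examined were pseudocounts of 0.1 and 0.5, other filters on low values, quantile normalization and median-of-ratios scaling, limma without trend and robust settings, array weights, the replicate number as a block, fits with only the compared libraries or with 2 groups, the erythroid and B cell list means as covariates, other thresholds, other list tests, and leaving out each library. After the data were seen, 4 more were added: voom (limma) on the recovered reads, edgeR's quasi-likelihood test on the recovered reads (version 4.0.16, TMM library sizes; 2832 genes higher and 2726 lower in CIC-NUTM2A against the mean of the others), leaving out CIC-NUTM2A replicate 3 and NUP98-KDM5A replicate 2 together, and the mean of the immediate early and stress list as a covariate.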

Results

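Marrow RNA was compared between mouse leukemias started by 5 different drivers, in 17 libraries. The share of leukemia cells in each library was not measured here. Transcripts described below for the leukemias of a driver are those of its marrow libraries, and may come from leukemia cells or other marrow cells. CIC-NUTM2A, the fusion the series is about and one found in an isolated myeloid sarcoma, was represented by 5 libraries. CIC is a transcriptional repressor of genes that respond to ERK signalling. The other drivers, each with 3 libraries, were AML1-ETO9a, CBFA2T3-GLIS2 with an activating JAK2, NUP98-KDM5A and MLL-AF6, all fusions known from acute myeloid leukemia. Recovered depth ran from 23.9 M reads (CBFA2T3-GLIS2/Jak2 replicate 1) to 74.8 M (CIC-NUTM2A replicate 3). The sample identifiers of the CIC-NUTM2A libraries carry a different prefix from those of all 12 other libraries, so a difference in collection or preparation that went with this prefix could not be separated from the driver.

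Libraries fell by driver. The mean Pearson correlation of log2(RPM + 1) over 16804 genes was 0.984 for the 22 pairs within groups and 0.837 for the 114 pairs between groups, a difference of 0.147 with a one-sided permutation p of 1e-05, the smallest that 100000 permutations can give. All 17 libraries correlated best with a library of their own group. The lowest correlation within a group was 0.962 and the highest between groups was 0.932.

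Of the 11 mouse genes that share a name with a part of a construct, 4 were higher in the group that received the construct. Jak2, a cytokine receptor kinase, was at 937 ± 58.8 RPM (SD, n = 3) in CBFA2T3-GLIS2/Jak2, and its mean log2 value lay 2.24 above that of all other libraries. Runx1t1, the gene of the ETO part, was 1.32 higher in AML1-ETO9a, at 1.88 ± 0.310 RPM (n = 3). Both had an adjusted p of 0.00809 in exact permutation tests over 11 genes. Glis2 was 0.97 higher in CBFA2T3-GLIS2/Jak2 (exact adjusted p = 0.0121) and Nup98 was 0.58 higher in NUP98-KDM5A (exact adjusted p = 0.0108). The Glis2 call was lost without CBFA2T3-GLIS2/Jak2 replicate 3 (difference 0.88) and the Nup98 call without NUP98-KDM5A replicate 3 (difference 0.52). The other 7 did not pass. Their log2 differences and exact adjusted p were 0.27 and 0.397 for Cic, −0.01 and 0.574 for Gm806 (listed for Nutm2), −0.60 and 0.445 for Runx1, 1.57 and 0.291 for Cbfa2t3, 0.20 and 0.537 for Kdm5a, 0.72 and 0.421 for Mll1, and −0.79 and 0.574 for Mllt4. A construct may hold human cDNA or only part of a gene, so its reads need not count to the mouse gene.

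CIC-NUTM2A leukemias were set apart from the mean of the 4 other drivers by high expression of the genes that CIC is known to repress. Etv4, Etv1 and Etv5, transcription factors of the ETS family, were at 878 ± 186, 191 ± 48.3 and 1308 ± 234 RPM (n = 5), and their group means in the other drivers did not exceed 1.03 RPM for Etv1, 2.01 for Etv4 and 32.1 for Etv5. Etv1 was listed at 0 in all AML1-ETO9a libraries. Their log2 differences were 8.37 for Etv4 (SE 0.19, adjusted p = 3.56e-14), 7.25 for Etv1 (SE 0.12, adjusted p = 2.04e-15) and 6.83 for Etv5 (SE 0.25, adjusted p = 9.05e-12). Vgf, which encodes a neuropeptide precursor, was at 418 ± 139 RPM against group means of at most 0.390 elsewhere (log2 difference 8.28, SE 0.17, adjusted p = 1.45e-14). Across all genes, 1900 were called higher and 1938 lower in CIC-NUTM2A.

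Of the 25 CIC targets and ERK feedback genes, 19 were higher, 1 was lower and 5 were not called, with a median log2 difference of 3.94. These counts were equal when adjusted over the list alone. The list passed the camera test (adjusted p = 5.37e-09; adjusted p = 0.388 with an estimated correlation). Dusp6, the ERK phosphatase, was at 820 ± 74.9 RPM in CIC-NUTM2A and at 316 ± 70.3 in NUP98-KDM5A, the next highest group (log2 difference 4.05, SE 0.16, adjusted p = 2.55e-11). Dusp4, of the same phosphatase family, was 4.69 higher. Among the Sprouty and Spred inhibitors of ERK signalling, Spry4 was 5.64 higher (SE 0.13), Spred3 4.61, Spred1 3.94, Spry2 2.06 and Spred2 1.60, and Spry1 was at 15.4 ± 3.25 RPM (adjusted p = 1.49e-05). Spry2 was nonetheless at 34.4 ± 4.95 RPM in CIC-NUTM2A and 41.9 ± 4.03 in MLL-AF6. The adaptor genes Shc4 and Shc3 (listed at 0 in AML1-ETO9a and MLL-AF6) were 6.73 and 4.95 higher, the receptor genes Lrp8 and Gpr3 3.22 and 2.40 higher, and the phosphatase gene Ptpn9 2.35 higher.

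The D-type cyclins of the list were both high. Ccnd1 was at 949 ± 216 RPM in CIC-NUTM2A and 93.3 ± 25.9 in NUP98-KDM5A, the next highest group (log2 difference 6.39, SE 0.19, adjusted p = 1.23e-12), and Ccnd2 was at 1490 ± 335 RPM against 393 ± 20.3 in AML1-ETO9a (log2 difference 3.95, SE 0.20, adjusted p = 2.71e-10). Dusp5, another ERK phosphatase of the list, fell by 1.74 on the log2 scale (SE 0.17, adjusted p = 2.81e-07) and stood at 14.0 ± 2.36 RPM. Ccne1 (0.25), Fosl1 (−0.15), Phlda1 (−0.43), Arl4c (0.67) and Maff (−0.30) were not called; Arl4c was called with the erythroid and B cell covariates (1.51). Spry1 was the member whose call rested on scaling, with a log2 difference of 0.97 under quantile normalization.

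**Figure D1:**
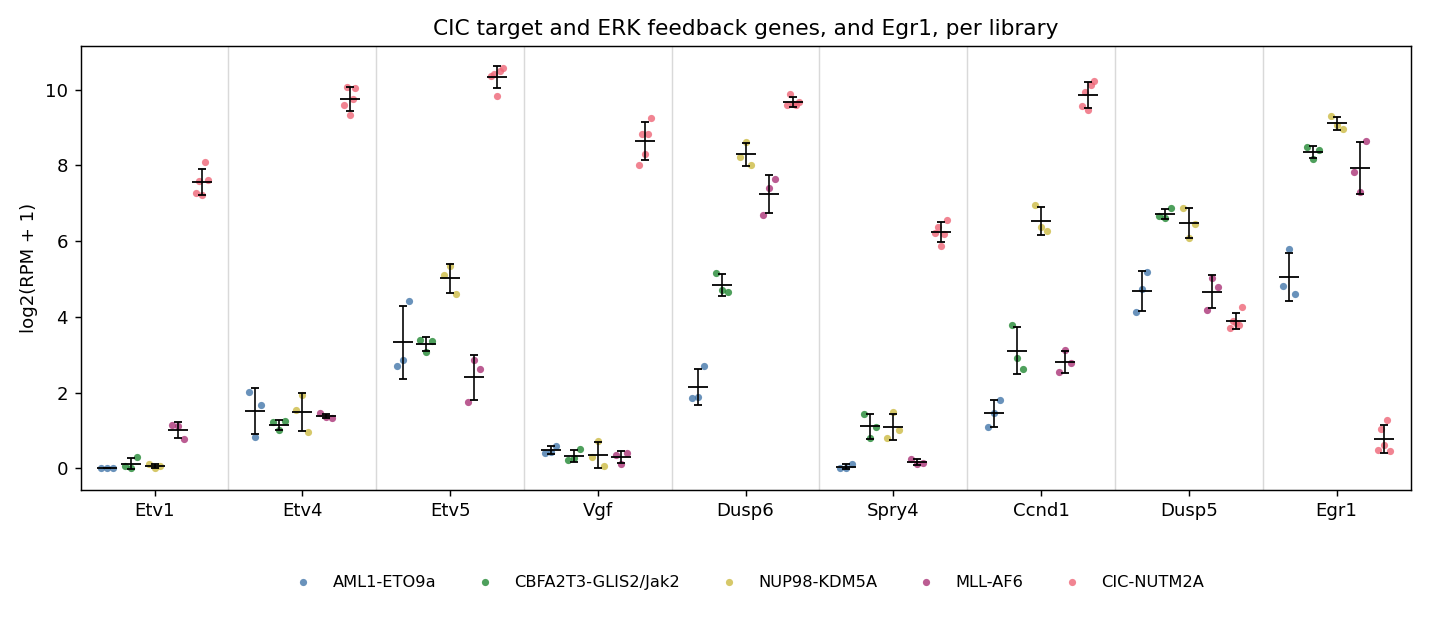
Levels of 8 CIC target and ERK feedback genes and of Egr1, as log2(RPM + 1) on the vertical axis, with 1 dot per library, coloured by driver, and black bars for the group mean ± SD (n = 5 for CIC-NUTM2A and 3 for each other group). Etv1, Etv4, Etv5, Vgf, Dusp6, Spry4 and Ccnd1 lie highest in CIC-NUTM2A, and Dusp5 and Egr1, which fell by 1.74 and 6.84 on the log2 scale, lie lowest.

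For a gene not picked by its call, chance separates 5 libraries from 12 in each direction in 1 of 6188 splits. Called genes were picked on the same libraries, so this rate does not apply to them. The same holds for the rates given with the comparisons below. Every CIC-NUTM2A library lay above all 12 others for 825 of the genes called higher, and below them for 679 of the genes called lower. Besides the CIC targets, the largest of these differences were in Mrc1, the macrophage mannose receptor (1912 ± 1139 RPM, log2 difference 7.63, SE 0.38), Cxcl13, a chemokine that attracts B cells (139 ± 93.8 RPM, 6.71), Scel (140 ± 50.5 RPM, 6.58), Gas6, the ligand of the TAM receptor kinases (132 ± 79.2 RPM, 6.54) and the glutathione transferase gene Gsta4 (133 ± 37.6 RPM, 6.52). Their adjusted p lay between 9.53e-12 and 6.45e-13 for Gsta4 and Scel and at 1.93e-10, 2.22e-10 and 1.72e-10 for Mrc1, Cxcl13 and Gas6.

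Among the genes lower without overlap that the naming rule ranks, Egr1 had the lowest difference in CIC-NUTM2A. This immediate early transcription factor was at 0.751 ± 0.460 RPM against group means of 34.8 to 554 (log2 difference −6.84, SE 0.22, adjusted p = 1.86e-12). Genes outside this ranking, such as Meis1, could lie lower than those that follow. In this ranking the cytokine receptor gene Il9r followed at −4.69 and the transcription factor gene Bcl11a at −4.62, with 3.61 ± 2.81 RPM in CIC-NUTM2A and 287 ± 44.7 in AML1-ETO9a. Cd274, which encodes the checkpoint ligand PD-L1, was at 2.70 ± 2.03 RPM in CIC-NUTM2A and 200 ± 11.1 in CBFA2T3-GLIS2/Jak2 (log2 difference −3.96, SE 0.25, adjusted p = 2.67e-09). The remaining genes of the 10 ranked in this way were Inpp4b (−4.37), Dnahc8 (−4.25), Cr2 (−4.19), Tgm2 (−4.02), Adamts3 (−3.96) and Hsph1 (−3.91). With the mean of the immediate early and stress list as a covariate, a setting chosen after the data were seen, 507 genes were higher and 187 lower; Etv1, Etv4, Etv5, Vgf and Egr1 were still called, and Il9r, Dnahc8, Cr2, Cd274 and Hsph1 were not. The number of genes called lower was 3108 with a pseudocount of 0.1, 3124 with voom on the recovered reads and 1195 with all other libraries taken as a single group.

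Genes of the HOXA cluster were low in CIC-NUTM2A, AML1-ETO9a and CBFA2T3-GLIS2/Jak2, and high in NUP98-KDM5A and MLL-AF6. Hoxa9 was at 0.108 ± 0.0852 RPM in CIC-NUTM2A, 0.0331 ± 0.0324 in CBFA2T3-GLIS2/Jak2, 142 ± 41.9 in NUP98-KDM5A and 171 ± 20 in MLL-AF6 (log2 difference −3.51, SE 0.11, adjusted p = 1.45e-12), and Hoxa6 was lower by a log2 difference of −3.20. Meis1, the HOX cofactor, was at 0.719 ± 0.431 RPM in CIC-NUTM2A, 530 ± 79.0 in MLL-AF6, 248 ± 36.2 in CBFA2T3-GLIS2/Jak2 and 0.135 ± 0.0824 in AML1-ETO9a (−5.15, SE 0.18, adjusted p = 4.63e-12). Another cofactor, Pbx3, was at 33.6 ± 5.13 RPM and not called (0.90). Of 12 tested members of the HOXA cluster and cofactors, 8 were lower and 4 not called (camera adjusted p = 0.00141; 0.533 as an adjusted p with an estimated correlation). That call was lost with voom (adjusted p = 0.120), with edgeR on the recovered reads (0.818), where Hoxa6 was not called, and with the other libraries as a single group (0.210), where neither Hoxa9 nor Hoxa6 was, and its adjusted p over the alternatives ranged from 9.18e-05 to 0.818. None of the 5 tested HOXB genes was called (adjusted p = 0.0530). Of 19 stem and progenitor genes, 14 were lower, 3 higher and 2 not called (adjusted p = 0.0190; adjusted p = 0.533 with an estimated correlation). Kit, the stem cell factor receptor, was at 13 ± 4.79 RPM (−3.72, SE 0.19), and Erg, at 1.72 ± 1.08 RPM, and Slamf1 (−2.50) were lower as well. The stem and progenitor call was lost with voom (adjusted p = 0.120) and edgeR (0.138; range over the alternatives 0.00302 to 0.138). Adjusted over the list alone, the counts of these 3 lists were equal.

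Transcripts of maturing myeloid cells were higher in CIC-NUTM2A than in the mean of the other drivers, though not than in each of them. The mean of the mature neutrophil list was 7.40 ± 0.54 on the log2 scale in CIC-NUTM2A and 7.50 ± 0.66 in NUP98-KDM5A, and that of the promyelocyte list was 6.57 ± 0.63 in CIC-NUTM2A and 8.34 ± 0.07 in MLL-AF6. Of 20 mature neutrophil genes 15 were higher and 5 not called, with a median log2 difference of 2.93 (adjusted p = 9.3e-05; adjusted p = 0.533 with an estimated correlation). Chi3l3, a chitinase-like protein of myeloid cells, was at 9207 ± 4637 RPM (5.02, SE 0.36, adjusted p = 1.05e-08), Cd177 at 665 ± 257 (3.95) and Lcn2, the neutrophil granule protein lipocalin, at 667 ± 346 (3.22). Levels of Chi3l3 in MLL-AF6 (8288 ± 2524) and of Lcn2 in NUP98-KDM5A (670 ± 151) were within the spread of the CIC-NUTM2A libraries. Of 20 monocyte and macrophage genes 15 were higher, 1 lower and 4 not called (adjusted p = 0.000395; adjusted p = 0.533 with an estimated correlation). The complement genes C1qa, C1qb and C1qc, abundant in tissue macrophages, were at 258 ± 134, 307 ± 144 and 247 ± 120 RPM, with log2 differences of 5.14, 5.21 and 5.06 and group means of at most 29.7 RPM in the other drivers. Of 10 promyelocyte granule genes 7 were higher and 3 not called (adjusted p = 0.0233; adjusted p = 0.555 with an estimated correlation). Elane, neutrophil elastase, was at 324 ± 178 RPM in CIC-NUTM2A (3.48, SE 0.41) and 1865 ± 399 in MLL-AF6, Prtn3, proteinase 3, at 219 ± 90.1 (2.55) and 1147 ± 137, and Cebpe, a granulocyte transcription factor, at 70.3 ± 25.8 (3.37); Mpo (0.36, adjusted p = 0.505), Ctsg (0.04, adjusted p = 0.899) and Srgn (−0.81) were not called. The promyelocyte call was lost with voom (adjusted p = 0.0754), with the other libraries as a single group (0.240) and without CIC-NUTM2A replicate 3 (0.0554), and its range over the alternatives was 0.00118 to 0.987. With the immediate early covariate the neutrophil (0.129) and promyelocyte (0.987) calls were lost, where the neutrophil range was 3.69e-07 to 0.129. Counts adjusted over the list alone were equal for all 3 lists.

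**Figure D2:**
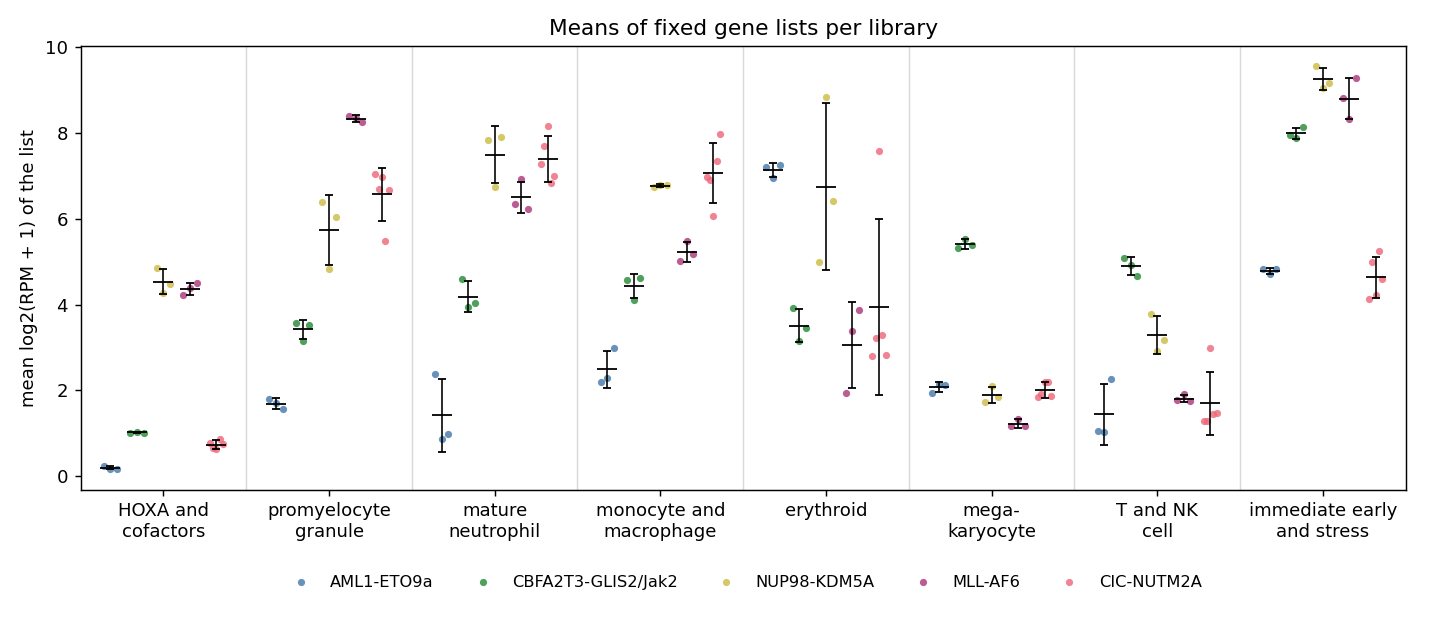
Means of 8 fixed gene lists per library, as mean log2(RPM + 1) on the vertical axis, with 1 dot per library, coloured by driver, and black bars for the group mean ± SD (n = 5 for CIC-NUTM2A and 3 for each other group). The HOXA list is high in NUP98-KDM5A and MLL-AF6 (4.54 and 4.37), the megakaryocyte list in CBFA2T3-GLIS2/Jak2 (5.41), and in the erythroid list CIC-NUTM2A replicate 3 (7.57) stands above the other CIC-NUTM2A libraries.

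Lymphoid transcripts were lower in CIC-NUTM2A than in the mean of the other drivers. Of 10 B cell genes 8 were lower and 2 not called (adjusted p = 0.00411; adjusted p = 0.533 with an estimated correlation), among them the B cell transcription factor gene Ebf1 (−3.42, SE 0.27, adjusted p = 2.86e-08), at 1.47 ± 1.44 RPM. The mean log2 value of the list was 2.86 in CIC-NUTM2A replicate 3 and 0.98 to 1.1 in the 4 others. Of 18 T and NK cell genes 11 were lower, 1 higher and 6 not called (adjusted p = 0.0233; adjusted p = 0.662 with an estimated correlation). The mean of this list was 1.69 ± 0.73 in CIC-NUTM2A, from 1.27 in replicate 1 to 2.99 in replicate 3, against 1.44 ± 0.71 in AML1-ETO9a, 1.81 ± 0.09 in MLL-AF6, 3.28 ± 0.44 in NUP98-KDM5A and 4.89 ± 0.21 in CBFA2T3-GLIS2/Jak2. The T and NK cell call was lost with voom (adjusted p = 0.0664), edgeR (0.166) and the replicate number as a block (replicate block, 0.0585) and without CIC-NUTM2A replicate 1 (0.0516), and turned to higher with the erythroid and B cell list means as covariates (0.0151), within a range over the alternatives of 0.000639 to 0.166. The same covariates, one of which is the B cell list itself, ended the B cell call (0.873; range 0.000106 to 0.873). MHC class II genes, 4 of 10 lower, were not called as a list (0.130), but were with array weights (0.0477) and without CIC-NUTM2A replicate 3 and NUP98-KDM5A replicate 2 together (0.0495; range 0.0477 to 0.225).

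Erythroid genes varied within groups. The mean log2 value of the list was 7.57 in CIC-NUTM2A replicate 3 and 2.79 to 3.29 in the other CIC-NUTM2A libraries, and 8.84 in NUP98-KDM5A replicate 2 and 4.99 and 6.41 in the other NUP98-KDM5A libraries. Hba-a1, an alpha globin gene, was at 2775 RPM in the former library and 3857 in the latter. Of 19 erythroid genes 6 were lower and 13 not called (adjusted p = 0.207); the list was called lower without CIC-NUTM2A replicate 3 (0.0031), without it and NUP98-KDM5A replicate 2 (0.000746), with array weights (0.0151) and with the immediate early covariate (4.86e-05), and over the alternatives adjusted p ranged from 4.86e-05 to 0.760. Leaving out both libraries, a setting chosen after the data were seen, gave 1959 genes higher and 1986 lower in CIC-NUTM2A.

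Among the other cell type lists, the megakaryocyte genes divided, with 2 of 15 higher, 7 lower and 6 not called (adjusted p = 0.153); the list was called lower when genes needed 5 RPM (0.0105) and with the immediate early covariate (0.0352; range over the alternatives 0.0105 to 0.695). Pf4, platelet factor 4, was among the higher ones at 126 ± 62.5 RPM (5.37, SE 0.31, adjusted p = 1.05e-09). Of 11 mast cell and basophil genes 6 were lower, 1 higher and 4 not called (adjusted p = 0.0530), with Hdc, the histamine-forming enzyme, at −3.17. The mast cell list was called lower without AML1-ETO9a replicate 1 (0.0391), AML1-ETO9a replicate 3 (0.0497) or CIC-NUTM2A replicate 3 (0.0297), without the latter and NUP98-KDM5A replicate 2 (0.0290), when genes needed 5 RPM (0.0231), with array weights (0.0477) and with the immediate early covariate (0.00304), in a range over the alternatives of 0.00304 to 0.387. Stroma and endothelium genes were higher in 9 of 11, lower in 1 and not called in 1 (adjusted p = 0.0203; adjusted p = 0.533 with an estimated correlation), with Sparc at 24.1 ± 3.59 RPM (3.28) and the collagen gene Col1a2 at 14.1 ± 9.09 (3.26). The mean of the list was 1.61 in CIC-NUTM2A replicate 3 and 3.11 to 3.42 in the 4 others, and 2.69 ± 0.17 in CBFA2T3-GLIS2/Jak2. This call was lost when genes needed 5 RPM (adjusted p = 0.0645) and with the erythroid and B cell covariates (0.203; range 4.86e-05 to 0.203). For each of the lymphoid, erythroid, megakaryocyte, mast cell and stromal lists, counts adjusted over the list alone were equal.

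Immediate early and stress genes were low in CIC-NUTM2A and in AML1-ETO9a. Fos was at 80.4 ± 39.6 RPM in CIC-NUTM2A and 74.9 ± 8.06 in AML1-ETO9a, against 1427 ± 180 to 2696 ± 345 in the 3 other groups (log2 difference for CIC-NUTM2A −3.56, SE 0.26, adjusted p = 1.09e-08). Fosb was at 25.2 ± 15.6 RPM (−5.01) and Atf3 at 5.84 ± 4.70 (−4.85). Of 16 members 14 were lower and 2 not called, equal when adjusted over the list alone (adjusted p = 1.33e-05; adjusted p = 0.533 with an estimated correlation). Mean list values were 4.64 ± 0.48 in CIC-NUTM2A, 4.79 ± 0.07 in AML1-ETO9a, 7.99 ± 0.13 in CBFA2T3-GLIS2/Jak2, 9.26 ± 0.26 in NUP98-KDM5A and 8.80 ± 0.48 in MLL-AF6. With the mean of this list itself as a covariate its call was lost and its sign turned (0.987; range over the alternatives 8.29e-08 to 0.987), as did the sign of Fos (0.16).

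Of 20 proliferation genes 4 were higher and 16 not called, with a median log2 difference of 0.54 (adjusted p = 0.000446; adjusted p = 0.533 with an estimated correlation). The mitotic genes Ccnb2 (1.35, SE 0.09), Birc5 (1.34, SE 0.12) and Cdk1 (1.23, SE 0.08) were among them, at 157 ± 16.3, 130 ± 17.3 and 241 ± 19.2 RPM. The mean of the proliferation list was 7.75 ± 0.10 in CIC-NUTM2A, 7.64 ± 0.09 in AML1-ETO9a and 7.45 ± 0.13 in MLL-AF6. It was 6.94 ± 0.22 in NUP98-KDM5A and 6.60 ± 0.09 in CBFA2T3-GLIS2/Jak2. Libraries of CIC-NUTM2A (lowest 7.62) and AML1-ETO9a (highest 7.71) overlapped. The call was lost with the immediate early covariate (0.522; range over the alternatives 1.09e-05 to 0.522). Of 20 MYC and ribosome biogenesis genes 2 were lower and 18 not called (adjusted p = 0.712); median (0.05) and test pointed up and the mean (−0.05) down, and with the immediate early covariate the list was called higher (0.0151; range 0.0151 to 0.964). Of 18 interferon response genes 1 was higher, 3 lower and 14 not called, and 2 were lower when adjusted over the list alone (adjusted p = 0.778); here the median (0.10) was positive and the mean (−0.13) and the test pointed down. With the erythroid and B cell covariates the interferon list was called higher (7.89e-05; range 7.89e-05 to 0.990). No mitochondrially encoded gene of 13 was called (adjusted p = 0.231); the list was called lower with the immediate early covariate (0.00314), with the erythroid and B cell covariates (0.0452) and without CIC-NUTM2A replicate 3 and NUP98-KDM5A replicate 2 together (0.0290; range 0.00314 to 0.413). Of 10 tested construct genes 1 was higher, 3 lower and 6 not called (0.203). The proliferation, MYC, mitochondrial and construct counts were equal when adjusted over the list alone.

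Sex-linked transcripts differed between groups and within CIC-NUTM2A. All 5 were called, Ddx3y and the 3 other Y-linked genes higher and Xist, which is expressed from the inactive X chromosome, lower, also when adjusted over the list alone; as a list they did not pass (0.195; range over the alternatives 0.0013 to 0.607). They passed without CIC-NUTM2A replicate 5 (0.0013), with the replicate number as a block (replicate block, 0.00242) and with the other libraries as a single group (0.0294). Xist was at 2197 to 4703 RPM in the 12 other libraries and at 3.93, 4.09, 0.146 and 7.64 in CIC-NUTM2A replicates 1 to 4, and at 545 in replicate 5. Ddx3y was at 151, 154, 141 and 141 RPM in CIC-NUTM2A replicates 1 to 4, at 0.8 in replicate 5 and at no more than 0.0330 in the other drivers.

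**Figure D3:**
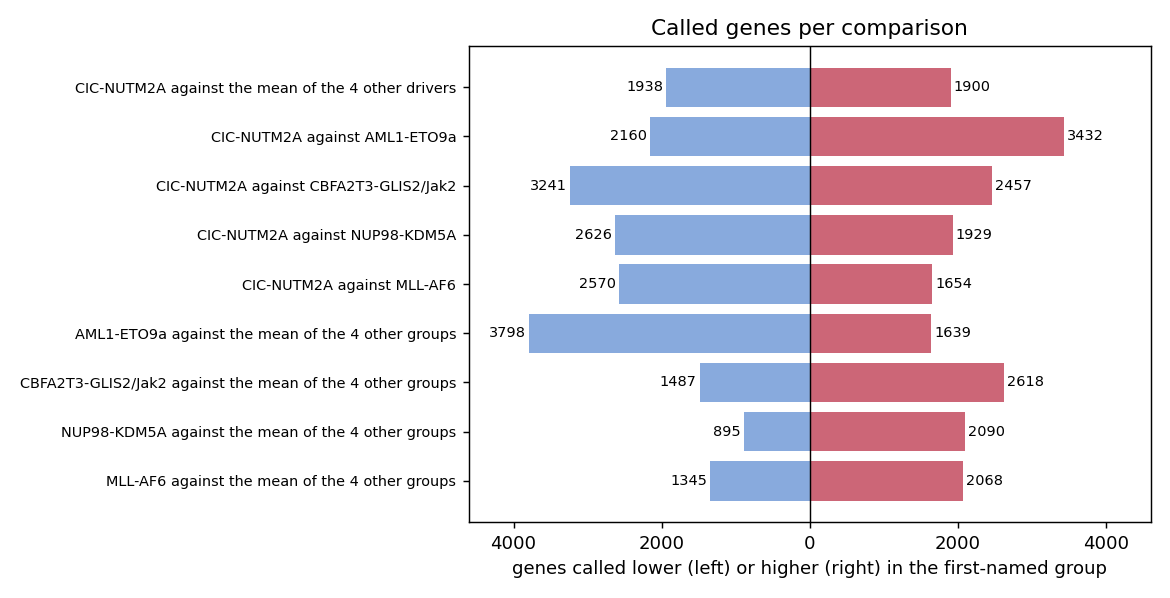
Genes called per comparison, out of 16804 tested, as bars to the right for genes higher and to the left for genes lower in the first-named group; the horizontal axis is the number of genes, starting at 0 on both sides. AML1-ETO9a has the most genes lower (3798) and, of the pairwise comparisons, CIC-NUTM2A against AML1-ETO9a the most higher (3432).

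Which genes set CIC-NUTM2A apart from every other driver was asked by calling each pair separately. In all 4 pairwise comparisons 482 genes were higher and 303 lower. Of the CIC target list 17 of 25 were among the higher ones, including Etv1, Etv4, Etv5, Dusp4, Dusp6, Spry4, Vgf, Ccnd1 and Ccnd2. Of the 20 monocyte and macrophage genes 6 were, including C1qa, C1qb, C1qc and Mrc1, and of the 20 mature neutrophil genes 4 were, including Ngp and Cd177. Among the lower genes were 5 of 10 B cell genes with Ebf1, 3 of 16 immediate early and stress genes (Egr1, Fosb and Hspa1b), and Kit, Hdc and Itgal. No gene of the HOXA, HOXB, promyelocyte, erythroid, proliferation or interferon lists was in either set. The 4 comparisons share the CIC-NUTM2A libraries. In 20 simulations at most 0 genes were found in either direction. They held no difference between any groups, so hardly any call was possible. Independent lists of the same sizes would share 5.67 higher and 9.96 lower, which leaves the sharing out. Neither value shows how much of the overlap comes from the shared libraries. When 2 CIC-NUTM2A libraries were compared with 2 of the drivers and the other 3 with the remaining 2, the 60 splits gave 275 to 343 genes higher and 262 to 328 lower. Together the 785 genes became 87 with the immediate early covariate, 1346 with a pseudocount of 0.1, 1410 with voom and 1407 with edgeR.

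Part of the small nucleolar RNAs and 2 long RNAs of the nucleus were low in CIC-NUTM2A; these were grouped after the data were seen, and the group was not tested as a list. Of 163 tested small nuclear and nucleolar RNAs, taken by name, 69 were lower, 1 higher and 93 not called against the mean of the other drivers (median −0.91; −0.79 with quantile normalization and −0.94 with median-of-ratios scaling), and 24 were lower than in each of them, which U1, U2, U4, U5, U6, U7, U11 and U12 were not. Malat1 and Neat1, long non-coding RNAs, were at 2103 ± 336 and 326 ± 160 RPM in CIC-NUTM2A (−2.70, SE 0.11, and −3.40, SE 0.28) against group means of at least 6195 and 800 RPM. Malat1 took 0.155% to 0.229% of the recovered reads in the 5 CIC-NUTM2A libraries and 0.407% to 1.86% in the 12 others. Genes that GENCODE M21 lists as protein-coding made up 12375 of all 16804 genes tested, 415 of the 482 higher than in all 4 drivers and 144 of the 303 lower. Genes under older symbols that GENCODE M21 lacks were not counted as protein-coding. A difference in RNA fraction or library preparation that went with the driver and its identifier prefix could not be separated from the driver. It may bear most on the genes called lower, which was not tested.

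Compared with AML1-ETO9a, CIC-NUTM2A leukemias had far more neutrophil and monocyte transcripts and, except for replicate 3, fewer erythroid ones. The erythroid list mean of that replicate (7.57) was above those of the 3 AML1-ETO9a libraries (6.96 to 7.26). Chi3l3 was at 8.89 ± 9.01 RPM in AML1-ETO9a (log2 difference 10.1, SE 0.50), and Ngp, a neutrophil granule protein gene, was at 4.49 ± 5.77 against 2321 ± 1773 RPM in CIC-NUTM2A (8.99, SE 0.59, adjusted p = 2.54e-09). Mrc1 (8.73) and Tmem119, at 397 ± 116 RPM in CIC-NUTM2A (8.57), were next. Of 20 mature neutrophil genes 19 were higher (adjusted p = 4.99e-08) and of 20 monocyte and macrophage genes all 20 (adjusted p = 4.45e-07); each had an adjusted p = 0.698 with an estimated correlation. CIC targets were higher in 20 of 25 (adjusted p = 1.37e-08; adjusted p = 0.438 with an estimated correlation). Car1, a carbonic anhydrase of red cell precursors, was at 1642 ± 261 RPM in AML1-ETO9a and 8.47 ± 16.9 in CIC-NUTM2A (−8.88, SE 1.07, adjusted p = 2.46e-06), and Scin (−8.32), Ephx2 (−8.24) and Bex4 (−7.91) were lower as well. Of 19 erythroid genes 10 were lower, 1 higher and 8 not called (adjusted p = 0.0178; adjusted p = 0.884 with an estimated correlation), and of 20 MYC and ribosome biogenesis genes 11 were lower and 9 not called (adjusted p = 2.2e-06; adjusted p = 0.698 with an estimated correlation). All these counts were equal when adjusted over the list alone. In total 3432 genes were higher and 2160 lower, of which 3345 and 2080 had no overlap between libraries. For a gene not picked by its call, chance gives this in 1 of 56 splits per direction. Quantile normalization gave 2816 higher and 3115 lower, moved the median difference of all genes from 0.04 to −0.14 and ended the erythroid call (0.127). That call was also lost with edgeR (0.251), the replicate number as a block (replicate block, 0.0670) and the erythroid and B cell covariates (0.684; range over the alternatives 8.26e-06 to 0.684).

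Against CBFA2T3-GLIS2/Jak2, Etv4 and Vgf of the CIC target list were among the 4 largest positive differences, and megakaryocyte, T and NK cell and MHC class II genes were lower in CIC-NUTM2A. Etv4 was 8.60 higher (SE 0.25), Tmem119 8.48, Vgf 8.32 and Chi3l3 7.73. Gzmb, the cytotoxic protease granzyme B, was at 4032 ± 422 RPM in CBFA2T3-GLIS2/Jak2 and 3.02 ± 3.87 in CIC-NUTM2A (−10.4, SE 0.74, adjusted p = 7.59e-09). Itga2b, the platelet integrin CD41, was at 2302 ± 215 and 2.78 ± 1.79 RPM (−9.36), Khdc1a at 664 ± 174 and 0.0268 ± 0.0174 (−9.31), and the interleukin 2 receptor gene Il2ra at 738 ± 145 and 0.443 ± 0.589 (−9.06). All 18 T and NK cell genes were lower (adjusted p = 2.18e-05) and all 10 MHC class II genes (adjusted p = 0.000405), each with an adjusted p = 0.473 with an estimated correlation. Megakaryocyte genes were lower in 10 of 15 and higher in 2 (adjusted p = 0.000204; adjusted p = 0.183 with an estimated correlation). CIC targets were higher in 19 of 25 and lower in 2 (adjusted p = 3.13e-07; adjusted p = 0.223 with an estimated correlation), and neutrophil genes higher in 17 of 20 and lower in 1 (adjusted p = 0.000159; adjusted p = 0.479 with an estimated correlation). Adjusted over the list alone these counts were equal. There were 2457 genes higher and 3241 lower (2423 and 3178 without overlap; chance 1 of 56 splits), and 1991 genes in all with the immediate early covariate. Median-of-ratios scaling moved the median of all genes from 0.01 to −0.11. With the erythroid and B cell covariates the T and NK cell call (0.491; range over the alternatives 1.71e-07 to 0.491) and the MHC class II call (0.573; range 1.49e-05 to 0.573) were lost.

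Set against NUP98-KDM5A, CIC-NUTM2A had lower levels of HOXA, HOXB and immediate early genes. HOXA genes and cofactors were lower in 9 of 12 with 3 not called, at a median log2 difference of −4.94 (adjusted p = 4.59e-07). All 5 HOXB genes (adjusted p = 7e-05) and all 16 immediate early and stress genes (adjusted p = 1.1e-08) were lower. Each of these lists had an adjusted p = 0.279 with an estimated correlation. Egr1 was lowest (−8.34, SE 0.30, adjusted p = 1.14e-11). The heat shock genes Hspa1b and Hspa1a, which are near-identical copies, were at 1630 ± 1743 and 771 ± 750 RPM in NUP98-KDM5A and 6.43 ± 4.91 and 3.84 ± 3.32 in CIC-NUTM2A (−7.51, SE 0.99, and −7.17, SE 0.92). The chemokine gene Cxcl2 was at 265 ± 139 and 0.737 ± 0.354 RPM (−7.16). Higher in CIC-NUTM2A were Vgf (8.29), Etv4 (8.27), Etv1 (7.50) and Shc4 (6.71), and 18 of 25 CIC targets, with 3 lower (adjusted p = 3.36e-06; adjusted p = 0.279 with an estimated correlation). Adjusted over the list alone, all counts stayed equal. In total 1929 genes were higher and 2626 lower (1832 and 2336 without overlap; chance 1 of 56 splits). Median-of-ratios scaling gave 1362 higher and 3186 lower, with the median of all genes at −0.12 in place of 0.04; with the immediate early covariate 134 genes were called, and that list itself was not (0.634; range over the alternatives 2.12e-12 to 0.634).

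MLL-AF6 leukemias also stood above CIC-NUTM2A in HOXA and immediate early genes. Meis1 was lower in CIC-NUTM2A (−8.30, SE 0.24, adjusted p = 7.68e-13), together with Hspa1b (3164 ± 2491 RPM in MLL-AF6, −8.73) and Hspa1a (1890 ± 1381 RPM, −8.66). Of 12 HOXA genes and cofactors 9 were lower and 3 not called (adjusted p = 3.57e-07; adjusted p = 0.309 with an estimated correlation), and all 16 immediate early and stress genes were lower (adjusted p = 3.57e-07; adjusted p = 0.368 with an estimated correlation). CIC-NUTM2A was higher in Mrc1 (9.13, SE 0.52), Etv4 (8.38), Vgf (8.35) and Etv5 (7.93). CIC targets were higher in 17 of 25 and not called in 8 (adjusted p = 1.17e-09; adjusted p = 0.309 with an estimated correlation), and stroma and endothelium genes higher in 7 of 11, lower in 1 and not called in 3 (adjusted p = 0.00534; adjusted p = 0.971 with an estimated correlation). Equal counts were found when adjusted over the list alone. There were 1654 genes higher and 2570 lower (1600 and 2508 without overlap; chance 1 of 56 splits). With the immediate early covariate 307 genes were called and the immediate early list was not (0.849; range over the alternatives 8.97e-10 to 0.849).

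The other drivers were each compared with the mean of the remaining 4 groups. AML1-ETO9a leukemias were marked by red cell precursor genes and by low levels of neutrophil, monocyte and most promyelocyte genes of the lists. Car1 was 8.09 higher (SE 0.94, adjusted p = 1.36e-06), the erythropoietin receptor Epor was at 136 ± 42.9 RPM (4.47, SE 0.56), and the erythroid transcription factors Gata1 and Klf1 were at 154 ± 8.72 (4.57) and 141 ± 19.4 RPM (4.74). Pax6, a homeobox gene of eye and brain development, was at 247 ± 33.7 RPM against group means of at most 0.719 (7.38, SE 0.13, adjusted p = 1.23e-15), Nmnat2, an enzyme of NAD synthesis, at 208 ± 7.23 (7.29), and Bex4 (7.41) and Ephx2 (6.97) were also among the 5 largest. Kit (3.06) and the interleukin 33 receptor gene Il1rl1 (5.35) were higher. Lowest were Chi3l3 (−7.54), Abca13 (−7.27), Ctsg, the granule protease cathepsin G, at 0.410 ± 0.349 RPM (−7.21), Serpinb1a (−7.05) and Igfbp4 (−6.99). The granulocyte transcription factor gene Gfi1 (−5.41), the lysozyme gene Lyz2 (−5.31), Meis1 (−5.85) and Hoxa9 (−3.67) were lower too.

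Of 19 erythroid genes 10 were higher, 1 lower and 8 not called in AML1-ETO9a (adjusted p = 0.00911), though NUP98-KDM5A replicate 2 (8.84) and CIC-NUTM2A replicate 3 (7.57) had higher list means than any AML1-ETO9a library. Of 20 MYC and ribosome biogenesis genes 16 were higher and 4 not called (adjusted p = 7e-08), with the nucleolar gene Nop58 at 527 ± 99.7 RPM (1.52, SE 0.10) and the lactate dehydrogenase gene Ldha at 1170 ± 120 (1.33, SE 0.08). All 20 mature neutrophil genes (adjusted p = 8.17e-07), all 20 monocyte and macrophage genes (adjusted p = 2.76e-05), 9 of 10 promyelocyte genes (adjusted p = 0.00109), 10 of 12 HOXA genes and cofactors (adjusted p = 2.76e-05) and all 16 immediate early and stress genes (adjusted p = 0.00016) were lower. Each of these 7 lists had an adjusted p = 0.566 with an estimated correlation, and equal counts when adjusted over the list alone. Overall counts were 1639 genes higher and 3798 lower, of which 1246 and 2398 had no overlap with any other library (chance 1 of 680 splits per direction). Quantile normalization gave 2767 higher and 2642 lower, moved the median of all genes from −0.11 to 0.16 (−0.27 with median-of-ratios scaling) and ended the erythroid call (0.0824), as did edgeR (0.137; range over the alternatives 5.88e-05 to 0.694). With the immediate early covariate 2614 genes were called, the erythroid list turned to lower without passing (0.694), and the immediate early list was not called (0.963; range 1.67e-06 to 0.963), while the HOXA call was lost with the other libraries as a single group (0.0582; range 3.47e-07 to 0.0582).

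CBFA2T3-GLIS2/Jak2 libraries were high in megakaryocyte, stem cell, lymphoid and interferon transcripts, and their cells of origin were not tested. Itga2b was 8.17 higher (SE 0.39, adjusted p = 6.24e-11), its platelet integrin partner Itgb3 was at 1418 ± 188 RPM (7.18), Vwf, von Willebrand factor, at 520 ± 34.5 (5.31) and the platelet glycoprotein gene Gp9 at 19.3 ± 3.98 (3.47). Mecom, the stem cell gene also called Evi1, was at 516 ± 48.9 RPM (7.05, SE 0.55), Mycn at 129 ± 21.1 (6.76) and Meis1 was 3.86 higher. The largest differences were in Gzmb (10, SE 0.65, adjusted p = 2.75e-09), Khdc1a (9.24), Il2ra (8.47), Prune2, at 1639 ± 119 RPM (8.43), and the fibroblast growth factor gene Fgf3, at 343 ± 26.2 RPM and listed at 0 in NUP98-KDM5A (8.38). Of the feedback genes that STAT5 induces, Socs2 was at 211 ± 23.6 RPM (4.66) and Cish at 122 ± 11.6 (3.95), and the kinase gene Pim2 was at 86.0 ± 0.680 (3.36), beside a Jak2 difference of 2.32. The interferon-induced gene Gbp2 was at 569 ± 22.8 RPM (6.27), and Ciita and Cd74 of antigen presentation at 223 ± 16.3 (3.42) and 1951 ± 183 (3.06). Klrb1c (4.15) and Nkg7 (4.13), genes of NK cells, and Mcpt4, a mast cell protease gene at 77.6 ± 23.1 RPM that was listed at 0 in AML1-ETO9a and NUP98-KDM5A (6.24), were higher. The lowest were the asparagine synthetase gene Asns, at 1.53 ± 0.342 RPM (−5.02), Epha2 (−4.32), Lpl (−4.24), Gsr, glutathione reductase, at 28.0 ± 5.55 (−4.14) and Amotl1 (−4.02).

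By list, CBFA2T3-GLIS2/Jak2 was higher in 12 of 15 megakaryocyte genes (adjusted p = 1.19e-06; adjusted p = 0.0553 with an estimated correlation), 13 of 19 stem and progenitor genes with 1 lower (adjusted p = 0.000165; adjusted p = 0.154 with an estimated correlation) and 9 of 12 JAK-STAT5 targets (adjusted p = 0.00168; adjusted p = 0.359 with an estimated correlation). All 18 T and NK cell genes (adjusted p = 3.11e-06) and all 10 MHC class II genes (adjusted p = 0.000127) were higher, each with an adjusted p = 0.399 with an estimated correlation, and so were 15 of 18 interferon response genes (adjusted p = 0.000595; adjusted p = 0.518 with an estimated correlation). Proliferation genes were lower in 6 of 20 and not called in 14, with a median of −0.87 and Mcm5, a replication helicase gene, at −1.39 (adjusted p = 3.11e-06; adjusted p = 0.399 with an estimated correlation). Neutrophil genes were lower in 15 of 20 and higher in 1 (adjusted p = 0.00383; adjusted p = 0.518 with an estimated correlation). For these 8 lists the counts adjusted over the list alone were equal. In total 2618 genes were higher and 1487 lower (1712 and 543 without overlap; chance 1 of 680 splits), and 2509 in all with the other libraries as a single group, where the neutrophil call (0.0874; 0.0706 with edgeR; range over the alternatives 0.00028 to 0.0874) and that of Meis1 were lost. Quantile normalization gave 2231 higher and 1931 lower with the median of all genes moved from −0.05 to −0.18, and the interferon call was lost with the erythroid and B cell covariates (0.847; range 2.84e-05 to 0.847).

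NUP98-KDM5A libraries held transcripts of HOXA and HOXB genes together with mature myeloid ones. Hoxa9 was 5.22 higher (SE 0.13, adjusted p = 3.78e-13), Hoxa6 was at 136 ± 47.2 RPM (5.50), and Hoxb6, Hoxb5 and Hoxb4 were 3.98, 3.97 and 3.20 higher, at 15.3 ± 3.13, 15.5 ± 5.40 and 31.0 ± 9.97 RPM; Hoxb5 was listed at 0 in AML1-ETO9a and CBFA2T3-GLIS2/Jak2, and Hoxb6 in AML1-ETO9a and MLL-AF6. The homeobox gene Nkx2-3, at 87.9 ± 29.9 RPM (6.40, SE 0.13), was listed at 0 in AML1-ETO9a. Thrombospondin 1 (Thbs1) was at 1385 ± 162 RPM (5.77) and fibronectin (Fn1) at 2029 ± 1176 (5.72). Lyz2 was at 3958 ± 493 RPM (3.90, SE 0.28), the macrophage colony-stimulating factor receptor gene Csf1r at 494 ± 83.4 (2.78), the granule gene Ltf at 1208 ± 690 (4.44), and the dendritic cell genes Cd209a (4.00) and Itgax (3.47) were higher. Among immediate early genes Fos was 2.93 and Klf2 3.58 higher. Lowest were Fnbp1l (−4.11), Ica1 (−3.45), Kalrn (−3.44), the corepressor gene Tle1, at 3.65 ± 1.97 RPM (−3.40), and Spns2 (−3.19).

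HOXA genes and cofactors were higher in 10 of 12 (adjusted p = 2.14e-08) and HOXB genes in 5 of 5 (adjusted p = 2.21e-06) in NUP98-KDM5A, each with an adjusted p = 0.205 with an estimated correlation. Neutrophil genes were higher in 19 of 20 (adjusted p = 6.94e-08; adjusted p = 0.389 with an estimated correlation), monocyte and macrophage genes in 14 of 20 with 1 lower (adjusted p = 1.65e-05; adjusted p = 0.392 with an estimated correlation), immediate early and stress genes in 16 of 16 (adjusted p = 2.14e-08; adjusted p = 0.248 with an estimated correlation) and B cell genes in 9 of 10 (adjusted p = 0.000353; adjusted p = 0.501 with an estimated correlation). Erythroid genes were higher in 13 of 19 (adjusted p = 0.00407; adjusted p = 0.684 with an estimated correlation), with Slc4a1, the red cell anion exchanger, at 1226 ± 1659 RPM (4.87, SE 1.15) and Hba-a1 at 1571 ± 1992 (3.63, SE 1.02). In replicate 2 the mitochondrial ribosomal RNA mt-Rnr2 took 16.9% of the recovered reads, and without this library neither the erythroid list (adjusted p = 0.101; range over the alternatives 1.68e-07 to 0.968) nor Hba-a1 (2.50) was called. The erythroid list was not called with edgeR either (0.0928). Adjusted over the list alone, the 7 counts were equal. There were 2090 genes higher and 895 lower (621 and 240 without overlap; chance 1 of 680 splits). Median-of-ratios scaling gave 2536 and 608, with the median of all genes moved from −0.11 to 0.06. The immediate early covariate left 614 genes called and ended the call of that list (0.484; range 2.91e-11 to 0.484), a fit with the other libraries as a single group left 967, without Hoxa9, Thbs1, Lyz2, Csf1r and Ltf among them, and the erythroid and B cell covariates ended the B cell call (0.979; range 1.72e-05 to 0.979).

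MLL-AF6 leukemias combined HOXA genes with the granule genes of promyelocytes. Hoxa9 was 5.59 higher (SE 0.13, adjusted p = 9.43e-14), Hoxa10 was at 59.9 ± 5.93 RPM (4.55) and listed at 0 in AML1-ETO9a and CBFA2T3-GLIS2/Jak2, and Meis1 was 5.23 higher. Elane was at 1865 ± 399 RPM (6.90, SE 0.49), Mpo, myeloperoxidase, at 1436 ± 450 (6.52), Prtn3 at 1147 ± 137 (5.67) and Ctsg at 1351 ± 95.8 (5.20), with Gfi1 at 211 ± 30.3 (3.63). Penk, the enkephalin precursor, at 418 ± 83.8 RPM (6.56), and Myo18b, at 233 ± 16.8 (6.31), were among the 5 largest differences. The adhesion molecule gene Ncam1, CD56, was at 193 ± 9.31 RPM (5.47). Ccnd2, at 10.7 ± 4.34 RPM, had the lowest difference (−4.84, SE 0.24, adjusted p = 3.43e-10), followed by the tight junction gene Tjp1 (−4.76), the laminin gene Lamc1 (−4.41), Hemgn (−4.29) and Serpinb6b (−4.18). The hedgehog receptor gene Ptch1 (−3.60) and Itga2b (−3.91) were lower.

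In MLL-AF6, HOXA genes and cofactors were higher in 9 of 12 (adjusted p = 1.11e-07; adjusted p = 0.219 with an estimated correlation), and promyelocyte genes in 9 of 10 (adjusted p = 4.65e-05) and immediate early and stress genes in 15 of 16 (adjusted p = 0.000125), each with an adjusted p = 0.469 with an estimated correlation. Megakaryocyte genes were lower in 9 of 15 (adjusted p = 2.84e-05; adjusted p = 0.144 with an estimated correlation) and erythroid genes in 11 of 19 (adjusted p = 0.00257; adjusted p = 0.749 with an estimated correlation). Each count was equal when adjusted over the list alone. The comparison gave 2068 genes higher and 1345 lower (1036 and 293 without overlap; chance 1 of 680 splits), 1819 in all with the immediate early covariate and 1129 with the other libraries as a single group, where Meis1, Prtn3 and Gfi1 were not called. Under the immediate early covariate the immediate early list turned to lower without passing (0.696; range over the alternatives 3.06e-06 to 0.696) and the erythroid list turned to higher without passing (0.708), a call also lost with the erythroid and B cell covariates (0.890; range 2.85e-05 to 0.890).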

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

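Of the tests in this part, those of a separate sample series, of handling from library to library and of XY cells in CIC-NUTM2A replicate 5 were chosen after the result was seen.

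In CIC-NUTM2A, the only group of more than 3 libraries, 15 of 117 values had a single library apart from the 4 others. Groups of 3 were not tested in this way. Chance gives about 1 in 20 for a single value. The values are not independent, as lists were tested beside genes they hold, so this rate does not apply to the tally. The number given is the gap to the nearest library as a share of the range of the group. Replicate 3 was apart in 11 of the 15. It was highest for the B cell list (0.940) with Ebf1 (0.790), for the erythroid list (0.895) with Car1 (0.810) and for the T and NK cell list (0.890). It was also highest for Bex4 (0.893), Il2ra (0.883), Cd274 (0.831), Slamf1 (0.806) and Inpp4b (0.715). It was lowest for the stroma and endothelium list (0.826). Replicate 5 was lowest for Ddx3y (0.981) and the sex-linked list (0.826) and highest for Ccr1, a chemokine receptor gene (0.728), and replicate 4 was lowest for the promyelocyte list (0.759).

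Immediate early and stress genes were low in CIC-NUTM2A, with Fos at 80.4 ± 39.6 RPM and Fosb at 25.2 ± 15.6 (n = 5). Handling that differed from library to library is argued against: the range of the list mean within a group averaged 0.128 of the range between group means. A separate series of samples, which the identifier prefix of CIC-NUTM2A may mark, stays open as a cause, because the prefix goes with the driver. AML1-ETO9a, which shares the prefix of the other drivers, had a list mean that differed by −3.90 from that of the 9 libraries of the 3 remaining groups, so the prefix need not be the cause of a low list. An effect of the driver stays open too, and handling that differed from group to group cannot be told apart from it, as each group is a single set of libraries.

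Xist and the Y-linked genes split along the groups, with Xist at 2197 to 4703 RPM in the 12 libraries of the other drivers and Ddx3y at 141 to 154 in 4 of the 5 CIC-NUTM2A libraries. In replicate 5, with Xist at 545 RPM and Ddx3y at 0.8, the Y-linked genes stood at 0.560% of their level in the other CIC-NUTM2A libraries, which argues against XY cells with the Y-linked transcripts of those libraries as over 10% of it. Its Xist level, between those of the other CIC-NUTM2A libraries and of the other drivers, stays open, and XY cells without a Y chromosome were not tested for. Sex of the donor cells and of the recipients stays open and was not tested, and this split goes with the driver in the comparisons of CIC-NUTM2A except for replicate 5. That library lacks the Y-linked transcripts and had a CIC target list mean of 6.81, against 6.28 to 6.76 in the 4 others.

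Mrc1, C1qa, C1qb and C1qc were high in CIC-NUTM2A, with 410 to 3226 RPM for Mrc1 and 106 to 472 for C1qa. Resident macrophages in the CIC-NUTM2A marrow may be the source of these transcripts. Of 9 further macrophage markers fixed before this test, 5 were higher than in the mean of the other drivers. They were Lgmn (3.96, at 608 ± 220 RPM), Mertk (2.45), Cd68 (1.84), Siglec1 (1.66) and Spic (1.09). Mertk and Cd68 had higher group means in NUP98-KDM5A (54.7 ± 65.0 and 115 ± 15.9 RPM) than in CIC-NUTM2A (38.6 ± 15.5 and 95.6 ± 23.2). For Mertk the SD in NUP98-KDM5A exceeded the mean, so that group mean is uncertain. Siglec1 and Spic in NUP98-KDM5A (12.4 and 6.53 RPM) were within the spread of the CIC-NUTM2A libraries (means 16.5 and 7.93). Cd5l (−0.34), Slc40a1 (−0.61) and Hmox1 (0.01) were not called, and Timd4 was too low to be tested. Apoe (2.47), Cd163 (3.91) and Fcgr1 (2.29), which were higher too, had been left out of these markers because their values had been seen. Markers of one cell type thus went apart, and neither resident macrophages nor expression by the leukemia cells could be excluded.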

How the results depend on the processing

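The voom and edgeR fits, the immediate early covariate and leaving out 2 erythroid-rich libraries together were chosen after the data were seen. Gene results were tallied only for genes named in the text, 196 results with a pseudocount of 0.1. Many were picked for large differences in the main fit, so most were likely to hold from the start. Over all alternatives, 6532 of these gene results held, 92 lost and 5 gained a call and 4 reversed. The immediate early covariate alone gave 56 of these losses and all 4 reversals. The reversed genes, Fos, Hspa1b and Hspa1a, belong to the list whose mean is the covariate, so their reversal is circular. Fits with only the compared libraries or 2 groups gave 27 of the losses. For lists the numbers held, lost, gained and reversed were 2442, 96, 34 and 7, and 29 of 374 counts moved by over 1.5 times. All 27 lists were tallied for CIC-NUTM2A against the mean, and elsewhere only lists chosen for the text. The other thresholds and limma without trend and robust settings do not enter the list tests. All 72 list results of each of these settings therefore held by construction. With estimated correlation each of the 56 list calls tallied here ended (CIC targets adjusted p = 0.388, where the other alternatives ranged from 2.47e-29 to 7.48e-08). With a pseudocount of 0.1, 3108 genes were lower in CIC-NUTM2A and 1346 differed from all 4 drivers; with voom, 3124 and 1410. With edgeR on the recovered reads, 2832 were higher and 2726 lower in CIC-NUTM2A and 1407 differed from all 4; 7 list calls and that of Hoxa6 ended, and the median of all genes moved from −0.03 to 0.07 in CIC-NUTM2A and from −0.11 to −0.00 in NUP98-KDM5A (0.03 with voom). With the other libraries as a single group, 1195 were lower in CIC-NUTM2A, and 2509, 967 and 1129 were called in CBFA2T3-GLIS2/Jak2, NUP98-KDM5A and MLL-AF6. Without a minimum difference, CIC-NUTM2A had 6006 higher and 6368 lower, the pairwise comparisons (AML1-ETO9a, CBFA2T3-GLIS2/Jak2, NUP98-KDM5A, MLL-AF6) 11603, 11925, 11413 and 10507, the other drivers in the same order 12918, 11075, 10675 and 10108, and all 4 pairs together 3155. With the immediate early covariate, which shares most of its variation with the groups, CIC-NUTM2A had 507 higher and 187 lower, 1991 against CBFA2T3-GLIS2/Jak2, 134 against NUP98-KDM5A, 307 against MLL-AF6 and 87 against all 4; AML1-ETO9a had 2614, NUP98-KDM5A 614 and MLL-AF6 1819. Under it the sign turned for Fos in CIC-NUTM2A (0.16) and NUP98-KDM5A (−0.34), for Hspa1b (0.99) and Hspa1a (1.43) in CIC-NUTM2A against NUP98-KDM5A, for the immediate early list in CIC-NUTM2A against the mean (adjusted p = 0.987) and MLL-AF6 (0.849) and in MLL-AF6 (0.696), and for the erythroid list in AML1-ETO9a (0.694) and MLL-AF6 (0.708). The T and NK cell (0.0151) and interferon (7.89e-05) lists turned to higher in CIC-NUTM2A with the erythroid and B cell covariates. For these changes the cause was not tested. Leaving out each library gave 1816 to 1969 genes higher and 1886 to 2037 lower in CIC-NUTM2A, pairwise 5473 to 5605, 5321 to 5744, 4397 to 4681 and 3972 to 4291, other drivers 5203 to 5520, 3716 to 4146, 2804 to 3229 and 3172 to 3456, all 4 pairs 749 to 837, CIC targets 1.41e-09 to 1.77e-08, similarity 0.141 to 0.154, and 3 to 4 construct genes. The replicate numbers do not pair the libraries: 30 same-number pairs had a mean residual correlation of 0.0112 and 60 others −0.00617. With the replicate number as a block (replicate block), calls ended for the T and NK cell list in CIC-NUTM2A (0.0585) and the erythroid list against AML1-ETO9a (0.0670), and the sex-linked list gained one (0.00242). The list test fry called 12 further lists in CIC-NUTM2A and lost the erythroid call in NUP98-KDM5A (0.0689).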

Other observations

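The tests of D-type cyclins and of the number of ETS family genes called were written before the result was seen, and that of a rise of all ETS genes after it.

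Lists without a call in CIC-NUTM2A against the mean of the other drivers still held single genes that differed. Of 18 adhesion and homing genes 9 were higher, 4 lower and 5 not called (adjusted p = 0.365). Ncam1, the adhesion molecule CD56, was at 54.9 ± 19.8 RPM (n = 5, log2 difference 3.14) and at 193 ± 9.31 in MLL-AF6. The chemokine receptor gene Ccr1 was at 137 ± 29.7 RPM (2.63) and 160 ± 19.2 in NUP98-KDM5A, and Itgal, the leukocyte integrin CD11a, was lower at 62.6 ± 18.2 RPM (−2.07). Of 11 dendritic cell genes 2 were higher, 4 lower and 5 not called (0.365), with Itgax, CD11c, lower by 2.82. Of 9 hedgehog and BMP genes 3 were higher, 2 lower and 4 not called (0.372), and of 12 JAK-STAT5 targets 2 were higher, 4 lower and 6 not called (0.292). Eosinophil genes were lower in 1 of 7 (0.224) and plasma cell genes in 2 of 6 (0.365). Counts adjusted over the list alone were equal for these 6 lists.

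Beside the high Etv1, Etv4 and Etv5 of CIC-NUTM2A, other members of the ETS family went both ways. Of 15 other ETS family genes, with Erg left out because its value had been seen, 4 were higher than in the mean of the other drivers (Ets2 1.66, Elk3 1.36, Sfpi1, which encodes PU.1, 1.23, and Fli1) and 2 lower (Ets1 −1.05 and Spib −2.38). Ets2 in NUP98-KDM5A (106 RPM) and Sfpi1 in NUP98-KDM5A (164) and MLL-AF6 (161) were nonetheless above CIC-NUTM2A (102 and 134). Elk3 and Fli1 had their highest group means in CIC-NUTM2A. A smaller rise of the family could thus be neither shown nor excluded. A rise of all members by about as much as in Etv1, Etv4 and Etv5, of which Etv5 had the lowest difference (6.83), is argued against. Over the 17 other ETS genes tested, Erg (−3), Erf (1.51) and Spic (1.09) included, the median was −0.0895 (SD 1.34) and the highest 1.66. Ccnd2 was low in MLL-AF6 (−4.84). Ccnd1 was at 6.12 ± 1.44 RPM there (−2.42, SE 0.23, adjusted p = 3.91e-07), between 1.78 ± 0.673 in AML1-ETO9a and 8.17 ± 4.14 in CBFA2T3-GLIS2/Jak2, and its difference comes from CIC-NUTM2A (949) and NUP98-KDM5A (93.3). Ccnd3, the remaining D-type cyclin gene, was at 152 ± 14.2 RPM and not called (0.27, SE 0.10, adjusted p = 0.0343). A rise of Ccnd3 RNA to the minimum difference was thus not seen. Ccnd3 had the highest level of the D-type cyclin genes in MLL-AF6, with Ccnd2 at 10.7 RPM. Whether it serves in place of Ccnd2 cannot be decided from its difference between groups.

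Other splits of the 17 libraries into groups of the same sizes were run for each comparison, 100 with the real one. The real split ranked highest, 1 of 100, for genes higher in CIC-NUTM2A (1900, highest other 272), genes lower (1938 and 847) and genes apart from all 4 drivers (785 and 0), and also for AML1-ETO9a (5437 and 886), CBFA2T3-GLIS2/Jak2 (4105 and 1315) and NUP98-KDM5A (2985 and 1235). For these counts every other split that was run gave fewer genes. Since libraries fell by driver, the other splits mix drivers, so this result mostly repeats that grouping. It also takes the libraries as independent, which the labels do not state. The CIC target list, tested with limma's camera in each permutation of the libraries, ranked 1 of 100 as well (p = 1.99e-10), a share under 0.05. Another split came close (3.88e-10), and the list had an adjusted p = 0.388 with an estimated correlation. For MLL-AF6, 2 of 100 splits gave as many (3413, highest other 3700), also a share under 0.05. The 3 libraries in the first group of that other split were those of AML1-ETO9a, so its size points to the structure of the samples. Of the 56 splits in each pairwise comparison, only the real one gave as many genes. It gave 5592 against AML1-ETO9a (highest other 358), 5698 against CBFA2T3-GLIS2/Jak2 (853), 4555 against NUP98-KDM5A (867) and 4224 against MLL-AF6 (406). The same limits hold for these splits.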
